A study of Ovis aries with 36 samples.

How the data were processed

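RNA was measured in 36 libraries of cultured sheep ruminal epithelial cells, 3 for each of 2 media at 6 time points. RNA was extracted with TRNzol, libraries were made with the TruSeq RNA v2 kit, which does not keep strand, and sequencing was paired-end on a NovaSeq, per the labels' protocols. HISAT2 2.2.1, SAMtools 1.20 and StringTie 2.1.5 were used, per the submitters' processing notes; which tool made the table and the genome build are not given in the sources used here. The deposited table holds a read count for each gene and library, made by the authors, with whole numbers for 35223 genes and no normalisation. Of these, 2778 carried an identifier and no symbol, and all 29910 distinct symbols were found in a RefSeq gene table of assembly ARS-UI_Ramb_v3.0, which was used only for names and for which genes overlap each other. No coordinates are given, and GC content was not analysed here.

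Groups were taken from the sample labels. Genes were filtered with filterByExpr of edgeR (minimum count 10, minimum total count 15, 12 groups), which left 22488, and scaled by TMM. CPM are counts scaled to library size with the TMM factors. Differences between the media were tested with edgeR quasi-likelihood tests (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on a model with a mean for each of the 12 groups, so that all comparisons shared an estimate of the spread: the mean of the 6 time points, each time point, and an F test of 5 contrasts for the dependence of the difference on time. For the 24 h component, a cosine and a sine of fixed 24 h period were fitted for each medium, and amplitude and peak time were taken from them with standard errors. The difference between the cosines of the media was tested over all genes. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and all tests are two-sided.

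The 40 gene lists covered the core clock and its outputs, VFA transport and metabolism, cell cycle, stress, inflammation, junctions, cell-type markers, ribosome and proteasome. Of their 936 members 51 had no entry in the table. Lists were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation and fry beside it, and the share of members with a 24 h component with Fisher's exact test. The lists, the tests, the rule for naming genes and most of the other settings tried were fixed before the data were examined, and those added later are named where they are used.

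Genes were named by rule: a symbol that is not an identifier and at least 5 CPM in a medium or group. For the mean, these were the 10 strongest rises and falls with a constant direction at 6 time points, and for each time point the 3 strongest each way with all libraries of the media apart. For the interaction they were the 6 smallest p, for the 24 h component all clock genes and the 8 largest amplitudes per medium, and for the different rhythm the 10 smallest p. For each list they were up to 4 members with the smallest p, with other members added as examples. Of 210 genes so named, 67 overlap another annotated gene, and without strand their reads cannot be told apart.

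The procedure was tested on simulated counts for 22488 genes, of which 200 were changed. For the mean comparison, 77.6% of genes changed 1.2-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold were recovered. The same shares at single time points were 43.3%, 74.6% and 95.5% at T0, 38.8%, 79.1% and 98.5% at T4, 46.3%, 68.7% and 93.9% at T8, 46.3%, 77.6% and 90.9% at T12, 41.8%, 80.6% and 87.9% at T16, and 32.8%, 83.6% and 95.5% at T20. For the interaction they were 19.4%, 62.7% and 87.9%. For amplitudes of 0.1, 0.2 and 0.5, 29.9%, 58.2% and 97% were recovered in Grain, 31.3%, 65.7% and 100% in Hay, and 11.9%, 41.8% and 78.8% for the different rhythm. Unchanged genes made up 0.877% to 7.79% of the edgeR calls. The 200 changes had directions drawn at random, whereas 18388 genes differed between the media in the data. Scaling and false calls under such widespread change were not simulated, so these shares may not hold for the data.

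The alternatives tried were DESeq2 1.42.0, DESeq2 size factors, no low-count filter, the replicate number as a block, the libraries of a time point or a medium fitted alone, a minimum fold of 2, a linear trend, any difference between time points, and leaving out each library.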

Results

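Gene expression was measured by RNA sequencing in cultured sheep ruminal epithelial cells. Ruminal epithelial cells line the forestomach and take up the volatile fatty acids (VFAs) released by rumen microbes. The cells were first kept for 2 h in serum-free medium with 100 nM dexamethasone, a glucocorticoid used to bring cellular clocks into step, and were then moved to a VFA medium. It had a pH of 7.2 and copied the rumen of sheep fed grain or hay. Grain medium had a stated VFA total of 115.78 mM, of which 16.0 mM was butyrate, 20.1 mM propionate and 71.1 mM acetate, with 5.3 mM isovalerate, 1.7 mM valerate and 1.1 mM isobutyrate. Hay medium had a stated total of 89.79 mM, of which 9.2 mM was butyrate, 14.6 mM propionate and 60.8 mM acetate, with 3.0 mM isovalerate, 1.2 mM valerate and 1.0 mM isobutyrate. Acetate, propionate and butyrate were given as sodium salts, so the media also differed in sodium, and cells without added VFAs were not analysed here. Harvests ran every 4 h from 24 h (T0) to 44 h (T20), with 3 libraries for each medium and time point, which gave 36 libraries in 12 groups. From which event these hours are counted is not stated clearly in the labels. The series title gives the purpose as the effect of VFA concentration on circadian gene expression, and 3 questions follow from the design. These are which genes differ between the media, whether that difference depends on the time of harvest, and which genes follow a 24 h course in each medium.

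Total counts per library ranged from 52.4 to 68.1 M, with means of 60.3 M ± 3.82 in Grain and 61.4 M ± 3.17 in Hay (SD, n = 18 each). Of the counted genes, 22488 of 35223 passed the low-count filter. Libraries of a group correlated across genes at 0.981 to 0.987 on the log scale. All 36 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 4.86 to 25.7). The first principal component held 46.4% of the variance and parted the media, and the second held 5.31%. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical.

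The most abundant transcript in both media was FN1, fibronectin, at 75025 ± 12418 CPM (counts scaled to library size) in Grain and 59792 ± 5022 in Hay (SD over 18 libraries here and for all CPM values of a medium). VIM, the mesenchymal intermediate filament vimentin, stood at 13167 ± 1127 CPM in Grain and 6375 ± 310 in Hay, and the collagen genes COL1A2 and COL3A1 stood at 3961 ± 950 and 3761 ± 990 in Grain. Keratins of basal keratinocytes were far lower, with KRT14 at 205 ± 57.9 CPM in Grain and 119 ± 6.17 in Hay and KRT5 at 83.3 ± 47.1 and 69.6 ± 20.0. The epithelial adhesion gene EPCAM stood at 28.3 ± 3.17 CPM in Grain and 23.1 ± 1.56 in Hay. The mesenchymal transcripts named here thus stood far above the epithelial ones, and which cell types the cultures held was not settled. Transcripts of blood cells were scarce, with the leukocyte gene PTPRC at 0.373 ± 0.188 CPM in Grain and 0.872 ± 0.293 in Hay (it overlaps another annotated gene and is uncertain).

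Averaged over the 6 time points, genes of the endoplasmic reticulum (ER) stress response were among the strongest rises in Grain, and mitochondrially encoded mRNAs were among the strongest falls. HSPA5, the main ER chaperone, rose by 2.70 on the log2 scale (SE 0.016, adjusted p = 5.56e-48), from 1336 ± 111 CPM in Hay to 8707 ± 1236 in Grain (n = 18 libraries each). HSP90B1, the ER member of the HSP90 family, rose by 2.38 (SE 0.016) from 1008 ± 143 to 5218 ± 497 CPM. ND3, a mitochondrially encoded subunit of respiratory complex I, fell by 3.77 (SE 0.032, adjusted p = 2.69e-44), from 193 ± 41.9 to 14.6 ± 4.92 CPM. TGFB2, a growth factor of the TGF-beta family, fell by 2.77 (SE 0.026), from 85.0 ± 11.0 to 12.5 ± 1.53 CPM. Each of these 4 genes had the same direction at all 6 time points.

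The 10 strongest rises by fold, among genes with at least 5 CPM in a medium and a constant direction, were DDIT3 (5.32, SE 0.25), MAFF (3.14), PRG4 (3.12), DES (3.12), CALCB (3.02), NR4A1 (2.75), PRR7 (2.70), HSPA5 (2.70), TONSL (2.65) and NMU (2.49). DDIT3 encodes CHOP, a transcription factor of the ER stress response. MAFF encodes a small bZIP partner, DES the muscle intermediate filament desmin, and NR4A1 an immediate early nuclear receptor. DDIT3 is uncertain because it overlaps another annotated gene, LOC541600, and its reads can pass between them. In Hay it had 35 to 86 counts in 11 libraries and 523 to 741 in the other 7. The sum of DDIT3 and LOC541600, chosen after these values were seen, rose by 3.75 (SE 0.027, edgeR adjusted p = 2.1e-46), from 15.5 ± 1.82 CPM in Hay to 216 ± 59.0 in Grain. The 10 strongest falls were RAD21L1 (-5.45), STEAP4 (-3.94), ND3 (-3.77), AMER3 (-3.48), NEFL (-3.13), DZIP3 (-2.86), ND2 (-2.81), TGFB2 (-2.77), PCSK1 (-2.75) and ATP8 (-2.75). PRG4, PRR7, RAD21L1 and ATP8 overlap another annotated gene and are uncertain for that reason.

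In all, 18388 of the 22488 genes differed at an adjusted p of 0.05 (edgeR quasi-likelihood test), 8522 higher and 9866 lower in Grain. A difference of at least 2-fold was met by 4887 of them, 1281 higher and 3606 lower. At this depth and with 18 libraries a medium, very small differences pass the test, and the median log2 fold change of all tested genes was -0.07. The fold change also followed abundance across genes (Spearman correlation with the mean log CPM 0.335). Its part in the excess of 2-fold falls and in the list directions that follow was not tested, and the list tests were not adjusted for it.

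**Figure D1:**
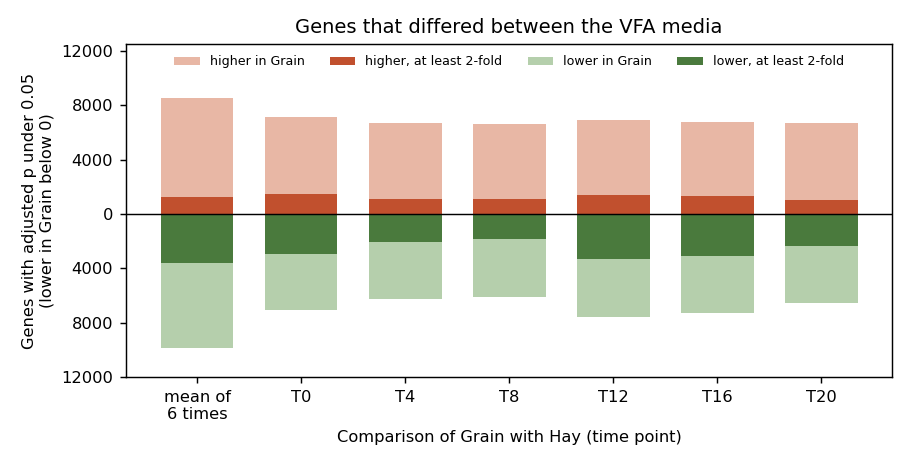
Genes past an adjusted p of 0.05 in the comparison of Grain with Hay, averaged over the 6 time points and at each time point. Bars above 0 count genes higher in Grain and bars below 0 genes lower in Grain, with those at least 2-fold apart in the darker shade. For the mean, 8522 genes were higher and 9866 lower, and 1281 and 3606 of these were at least 2-fold apart.

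Genes of the unfolded protein response, which refold or clear proteins in the ER, rose together: of 22 tested, 18 rose, 2 fell and 2 did not pass (camera adjusted p = 2.26e-15). HERPUD1, an ER degradation factor, rose by 2.36 (SE 0.016) and CANX, the chaperone calnexin, by 1.12 (SE 0.014), while CREB3L2 (-0.43) and PDIA6 (-0.18) fell. In the integrated stress response, the ATF4 programme of amino acid supply, 23 of 28 rose, 4 fell and 1 did not pass (adjusted p = 2.32e-06). ATF3 was up by 1.47 (SE 0.015), ATF4 by 0.82 (SE 0.012) and ASNS, asparagine synthetase, by 0.68 (SE 0.014). DDIT4, an inhibitor of mTORC1, was down (-1.34, SE 0.043). Among genes of mitosis, 38 of 39 rose and PTTG1 alone did not pass (0.06; adjusted p of the list 5.29e-14). The proliferation marker MKI67 was up by 2.00 (SE 0.069), from 1.81 ± 0.491 to 7.63 ± 3.13 CPM, and TOP2A, a DNA topoisomerase, up by 1.20 (SE 0.018). Among genes of DNA replication and S phase, 34 of 40 rose, 3 fell and 3 did not pass (adjusted p = 6.97e-09). The replication clamp PCNA was up by 1.33 (SE 0.022) and the licensing factor CDC6 by 1.71 (SE 0.069), and the cyclin CCNE2 down (-0.88, SE 0.030). In cholesterol synthesis, 18 of 23 genes rose and 5 fell (adjusted p = 0.000157). TM7SF2, a sterol reductase, was down (-0.76, SE 0.046). All 53 ribosomal protein genes tested rose, from 0.21 for RPL38 to 1.01 for RPL10 (adjusted p = 4.43e-25). The call was lost at an adjusted p = 0.0859 with an estimated correlation. The other 5 lists kept their call with an estimated correlation, at adjusted p values of 0.000852 for mitosis and the unfolded protein response, 0.000858 for S phase, 0.0108 for the integrated stress response and 0.0206 for cholesterol synthesis. Of the genes named in these lists, CANX, PDIA6, ATF3, ATF4, CCNE2 and RPL10 overlap another annotated gene and are uncertain.

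All 13 mitochondrially encoded mRNAs were lower in Grain (adjusted p = 1.84e-36, and 0.00214 with an estimated correlation), from -0.95 for COX1, a subunit of cytochrome c oxidase, to -3.77 for ND3. They made up 3.09% ± 0.194 of all counts in Hay and 1.11% ± 0.171 in Grain (SD, n = 18 each), whereas the mitochondrial ribosomal RNAs made up 0.283% ± 0.0700 and 0.320% ± 0.0335. Nuclear genes of oxidative phosphorylation went both ways, 10 of 27 up, 15 down and 2 not past (adjusted p = 0.354), with NDUFV2 at -0.76 and NDUFS3 at 0.70. Interferon response genes were lower in Grain, 18 of 28 down, 7 up and 3 not past (adjusted p = 0.00107, and 0.0108 with an estimated correlation). The antiviral GTPase MX1 was down (-1.42, SE 0.024), while the immunoproteasome subunit PSMB8 was up by 0.63 (SE 0.057). Of 28 inflammatory genes, 19 fell, 8 rose and 1 did not pass (adjusted p = 0.00225, and 0.0317 with an estimated correlation). The cytokine IL6 (-1.70, SE 0.044), the neutrophil attractant CXCL8 (-1.45, SE 0.020) and PTGS2, the inducible cyclooxygenase (-1.23, SE 0.022), fell, and NFKB2 (1.23, SE 0.024) and RELB (1.07, SE 0.047), subunits of the noncanonical NF-kB pathway, rose. Among genes known to be induced by inhibitors of histone deacetylases, the enzyme class that butyrate inhibits, 12 of 16 fell, 3 rose and 1 did not pass (adjusted p = 9.83e-06, and 0.00661 with an estimated correlation). ANXA1 (-2.64, SE 0.017) and TXNIP (-1.46, SE 0.013) fell, and KLF2 (1.93), KLF4 (0.74) and CCN2 (0.41) rose. The NRF2 antioxidant list had 16 of 26 down, 9 up and 1 not past (adjusted p = 0.0188, lost at an adjusted p = 0.225 with an estimated correlation). The heme oxygenase HMOX1 was down (-1.52, SE 0.033) and OSGIN1 up by 2.48 (SE 0.079). The osmotic stress list had 8 of 14 down, 5 up and 1 not past (adjusted p = 0.0284, lost at an adjusted p = 0.126 with an estimated correlation). The kinase SGK1 was down (-1.38, SE 0.014) and the inositol transporter SLC5A3 up by 0.63 (SE 0.018). Both calls were also lost without the low-count filter (adjusted p = 0.062 and 0.234). COX1, IL6, PTGS2, NFKB2, ANXA1, TXNIP, CCN2, OSGIN1 and SLC5A3 overlap another annotated gene and are uncertain.

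**Figure D2:**
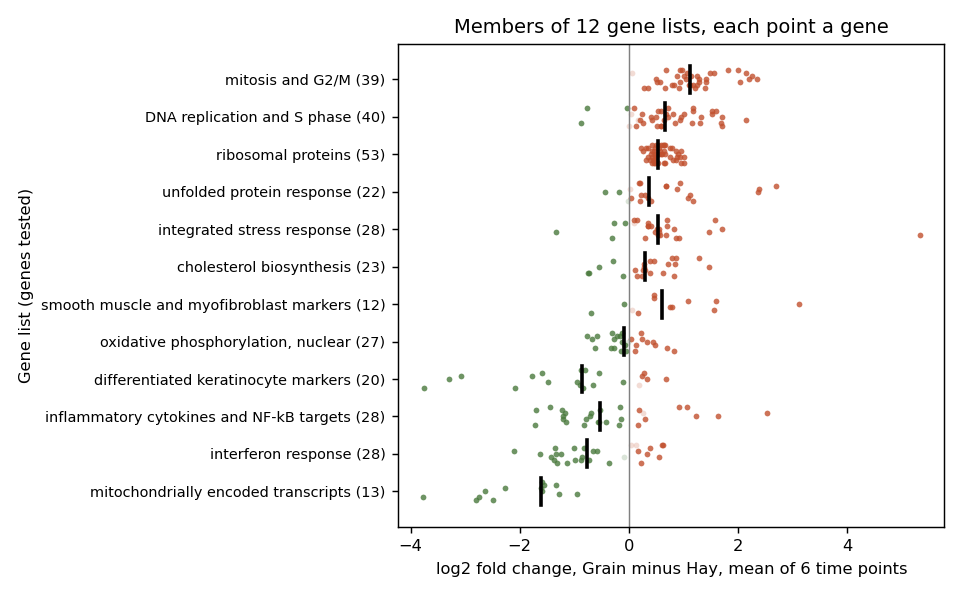
Log2 fold changes (Grain minus Hay, mean of 6 time points) of the tested members of 12 gene lists. Each point is a gene, right of 0 when higher in Grain, pale when its adjusted p was not under 0.05, and the black bar is the median of the list, 1.11 for mitosis, 0.54 for ribosomal proteins and -1.61 for the mitochondrially encoded mRNAs.

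Genes of VFA and acid transport changed one by one with no direction as a list: of 27 tested, 7 rose, 16 fell and 4 did not pass (adjusted p = 0.568). SLC16A1, the monocarboxylate transporter MCT1, was lower in Grain (-0.50, SE 0.015; 84.5 ± 5.93 against 120 ± 10.2 CPM), as was the bicarbonate cotransporter SLC4A7 (-0.76, SE 0.015). SLC4A7, with BDH1 and HK2 of the lists that follow, overlap another annotated gene and are uncertain. In activation and oxidation of short-chain acids, 8 of 25 rose, 14 fell and 3 did not pass (adjusted p = 0.081), with CPT2 (-0.99), an enzyme of beta-oxidation, down. In ketone metabolism 3 of 8 rose, 3 fell and 2 did not pass (adjusted p = 0.445), with the ketone enzymes BDH1 (-1.06) and OXCT1 (-0.65) down. Fatty acid synthesis had 7 of 13 up, 5 down and 1 not past (0.929). Glycolysis had 11 of 20 up and 9 down (0.805; HK2, hexokinase, 1.34 and LDHA, lactate dehydrogenase, -0.58), and the TCA cycle 9 of 21 up, 10 down and 2 not past (0.929). The same lack of a list direction was found for CDK inhibitors and p53 targets (9 of 19 up, 7 down; adjusted p = 0.464), apoptosis (14 of 20 up, 5 down; 0.233), heat shock (5 of 16 up, 10 down; 0.913), glucocorticoid targets (11 of 19 up, 7 down; 0.97), and hypoxia targets (9 of 21 up, 10 down; 0.913). It was found for histone deacetylases and acetyltransferases (10 of 24 up, 10 down; 0.913), tight and adherens junctions (9 of 22 up, 9 down; 0.58) and desmosomes (5 of 20 up, 13 down; 0.871). It was also found for growth factor and immediate early genes (18 of 29 up, 10 down; 0.97), TGF-beta targets (9 of 19 up, 10 down; 0.568), autophagy and lysosome (14 of 26 up, 10 down; 0.568) and the proteasome (13 of 31 up, 17 down; 0.913).

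Genes of the cell-type marker lists also differed between the media. Of 25 fibroblast and mesenchymal markers 17 rose and 8 fell in Grain (adjusted p = 0.000444, lost at an adjusted p = 0.314 with an estimated correlation). VIM was up by 1.04 (SE 0.014) and periostin, POSTN, by 1.59 (SE 0.021), and the collagen genes COL1A1 (-0.74, SE 0.015; it overlaps another annotated gene) and COL1A2 (-0.74, SE 0.011) down. Of 12 smooth muscle and myofibroblast markers 9 rose, 2 fell and 1 did not pass (adjusted p = 0.000103, lost at an adjusted p = 0.0859 with an estimated correlation). DES was up by 3.12 (SE 0.035) and ACTA2, smooth muscle actin, down (-0.69, SE 0.019). Basal keratinocyte markers (9 of 16 up, 7 down; adjusted p = 0.0764), differentiated keratinocyte markers (4 of 20 up, 15 down, 1 not past; 0.194), simple epithelial markers (2 of 9 up, 6 down, 1 not past; 0.0578), endothelial markers (4 of 12 up, 6 down, 2 not past; 0.868) and immune cell markers (3 of 16 up, 9 down, 4 not past; 0.901) had no list direction. Among their members, the basal gene CD44 rose by 1.55 (SE 0.019). The differentiated keratinocyte marker KRT13 fell (-0.89, SE 0.042, at 10.5 ± 1.90 against 19.2 ± 1.46 CPM), and so did KRT8, a keratin of simple epithelia (-1.22, SE 0.025). The simple epithelial list was called as lower in Grain without the 6 T12 libraries (camera adjusted p = 0.0282). It was called too without Grain T0 replicate 2 (0.0444), Hay T4 replicate 2 (0.0482) or Hay T8 replicate 3 (0.0495). Of signs of RNA makeup, long non-coding RNAs took 2.03% ± 0.226 of the counts in Hay and 1.34% ± 0.169 in Grain.

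Across the 40 lists, 14 had a direction against the other genes, 8 up and 6 down, and 9 of them kept the call with an estimated correlation. The number of members past the threshold, adjusted over the list alone, equalled that over all genes in every list except the integrated stress response, where 24 in place of 23 rose. The rotation test fry, which asks only whether the members of a list move on balance in a single direction and compares the list with no other gene, called 36 of 40. The median, the mean and the camera direction differed in sign for fatty acid synthesis (median 0.30, mean -0.03, up), the TCA cycle (-0.01, 0.02, up), heat shock (-0.27, 0.05, down), junctions (0.07, -0.07, down), endothelial markers (-0.18, -0.10, up), immediate early genes (0.16, 0.10, down), TGF-beta targets (-0.14, -0.10, up) and the proteasome (-0.04, 0.0033, down), none of which camera called.

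At single time points the same few genes led the differences. DDIT3 was among the 3 strongest fitted rises at every time point, from 3.69 (SE 0.55) at T12 to 7.17 (SE 0.75) at T20, but its size and rank there are uncertain. They follow how reads were shared with LOC541600 in Hay, where DDIT3 had 554 and 680 counts in 2 of the 3 T12 libraries and 53 or fewer in all 3 at T20. RAD21L1, a meiotic cohesin subunit, was among the 3 strongest falls at every time point, from -4.46 (SE 0.17) at T8 to -7.60 (SE 0.33) at T12. The size at T12 is not firm, since Grain there was at the floor (0.0471 ± 0.0815 CPM, SD, n = 3). MAFF rose by 3.53 (SE 0.13) at T0, 3.41 at T4, 3.27 at T8 and 3.12 at T20, and PRG4 by 3.67 (SE 0.16) at T0, 3.49 at T12 and 3.15 at T20. DUSP2, a phosphatase of MAP kinases, joined the 3 strongest rises at T4 (3.21, SE 0.17) and T8 (3.37, SE 0.17), CDRT4 at T12 (3.57, SE 0.20) and T16 (3.97, SE 0.21), and NR4A1 at T16 (3.32, SE 0.078). ND3 stood among the 3 strongest falls at T0 (-3.76), T4 (-3.97), T8 (-3.99), T16 (-3.81) and T20 (-3.61), the metalloreductase gene STEAP4 at T0 (-4.41), T12 (-4.31), T16 (-4.64) and T20 (-4.04). AMER3 was among them at T4 (-5.40) and T8 (-5.24), and DZIP3 at T12 (-3.75, SE 0.090). In each case all 3 Grain libraries lay on one side of all 3 Hay libraries, and each gene had an edgeR adjusted p of 3.44e-07 or smaller at that time point.

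The number of genes that differed was 14127 at T0 (7106 higher and 7021 lower in Grain), 12987 at T4 (6715 and 6272), 12766 at T8 (6645 and 6121), 14463 at T12 (6915 and 7548), 14108 at T16 (6798 and 7310) and 13238 at T20 (6682 and 6556). Which direction held more genes depended on scaling: with DESeq2 size factors the lower genes outnumbered the higher at every time point, as at T0 (6660 higher and 7463 lower), T4 (6231 and 6769), T8 (6110 and 6662) and T20 (6279 and 6929). Of the tested genes, 8763 passed at all 6 time points in the same direction, where independent lists of these sizes would share 34.3.

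The difference between the media depended on the time point for 7322 genes (F test of 5 contrasts). SERPINB1, a protease inhibitor of the serpin family, was higher in Grain at T0 (0.34, SE 0.035), T4 (0.43) and T8 (0.50) and lower at T12 (-0.90, SE 0.035) and T16 (-0.47), with -0.06 at T20 (adjusted p = 0.171), and had the smallest interaction p (adjusted p = 2.48e-22). The cytokine IL1A was lower in Grain throughout, by -1.70 (SE 0.040) at T4 and -0.38 (SE 0.039) at T12, with its largest fall at T8. Also lower throughout, with these values at T8 and T12, were the heat shock gene HSPA1A, which overlaps HSPA1L and is uncertain (-1.88 and -0.32), the transcription factor SOX4 (-2.15 and -1.17) and SGK1 (-1.99 and -0.71). LRRC58 was higher throughout, by 0.14 (SE 0.052) at T8 and 2.01 (SE 0.053) at T12. Of the 7322 genes, 821 were higher in Grain at some time point and lower at another, 3339 were higher at some and lower at none, and 3161 were lower at some and higher at none.

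Over the 20 h from T0 to T20, a cosine of fixed 24 h period fitted 7157 genes in Grain and 4647 in Hay at an adjusted p of 0.05 (edgeR quasi-likelihood F test). With the 18 libraries of each medium fitted alone the order turned, 5054 genes in Grain and 6233 in Hay, so neither medium can be said to hold more. The largest amplitudes in Grain, on the log2 scale from mean to peak, were those of AMER3 (1.66, SE 0.22, peak 14.8 h after T0), ACOT6 (1.55, SE 0.50), STEAP4 (1.19, SE 0.17, peak 5.70 h), RAD21L1 (1.15, SE 0.30), ABHD15 (1.13, SE 0.18), GAL (1.07, SE 0.11, peak 4.59 h), TNK1 (1.02, SE 0.22) and ZAR1 (0.96, SE 0.22). ACOT6, RAD21L1, ABHD15, TNK1 and ZAR1 overlap another annotated gene and are uncertain. The call of RAD21L1 was lost when Grain libraries were fitted alone (adjusted p = 0.0617). That of ACOT6 was lost without Grain T20 replicate 2 (0.0791) or 3 (0.0918), and that of TNK1 without the 6 T12 libraries (0.0544). The largest amplitudes in Hay were those of genes of the contractile apparatus and others that peaked at about the same hour: ACTG2 (1.57, SE 0.18, peak 15.2 h), the cytokine IL11 (1.11, SE 0.15, 14.3 h), TAGLN (1.05, SE 0.12, 15.9 h), ACTA2 (0.99, SE 0.15, 15.3 h), TPM2 (0.97, SE 0.11, 15.7 h), KLF2 (0.95, SE 0.081, 14.8 h), GLDN (0.85, SE 0.11, 15.3 h) and CRNN (0.82, SE 0.11, 15.8 h). ACTG2 overlaps another annotated gene. With 6 time points over 20 h the period was assumed and not estimated.

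The fitted peaks fell into a pair of windows on opposite sides of the day. In Grain 47.9% of the genes peaked 2 to 8 h and 43.4% 14 to 20 h after T0, and in Hay 33.7% and 51.8%. Median amplitudes were small, 0.20 in Grain and 0.16 in Hay, and 986 and 203 genes reached 0.5. A peak in these windows is also what a step between neighbouring time points gives, and the step from T8 to T12 was larger than any other between neighbouring times. It held 11245 genes in Grain and 8110 in Hay against 110 to 4668 for the other steps, T20 to T0 included. Any difference between the 6 time points was called for 11579 genes in Grain and 7927 in Hay.

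**Figure D3:**
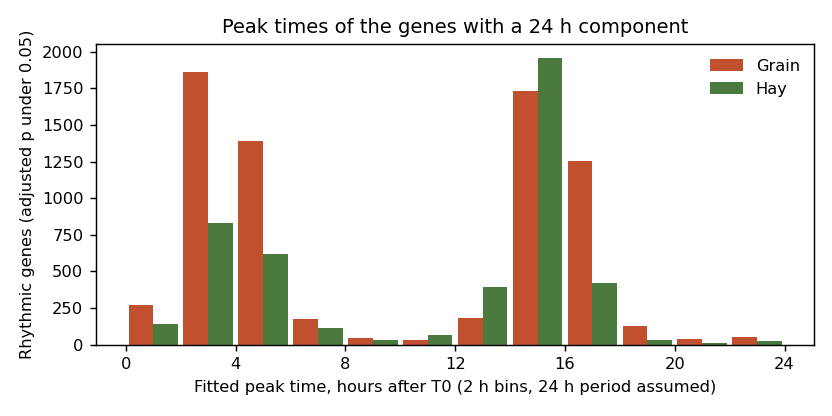
Number of genes with a 24 h component (adjusted p under 0.05) in each medium by fitted peak time in hours after T0, in bins of 2 h. The bars of both media gather in 2 windows, with 1859 Grain genes at 2 to 4 h and 1729 at 14 to 16 h, and 1954 Hay genes at 14 to 16 h.

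Of the genes with a 24 h component, 2071 had it in both media, where independent lists would share 1479, and 84.4% of these peaked within 4 h of each other in the media. Peaks of both media gathered in the same pair of windows, which by itself brings many peaks close. The count of 1479 also does not allow for abundance, which helps a gene to be called in both. How much of the overlap and closeness this gives was not tested. The test of the difference between the cosines of the media called 2550 genes, 337 of them rhythmic in both media. For 9 of the 10 with the smallest p, all but SERPINB1, a component was called in both media and the peaks lay on opposite sides of the day. HNRNPLL, a splicing regulator, peaked at 4.33 h in Grain (amplitude 0.29, SE 0.036) and 16.4 h in Hay (0.19, SE 0.034; adjusted p of the difference 1.81e-06), and RAP1GDS1, an exchange factor of small GTPases, at 4.16 and 14.7 h. MPV17L peaked at 2.19 h in Grain and 15.3 h in Hay, ANKRD22 at 3.40 and 14.7 h, DGCR8, a subunit of the microRNA processor, at 1.64 and 15.8 h, and SLC66A3 at 4.39 and 17.2 h. RASL11B, THRAP3 and JMJD1C had the reverse order, with peaks in Hay at 4.20, 2.65 and 1.85 h and in Grain at 17.4, 15.3 and 16.1 h. SERPINB1 peaked at 15.1 h in Hay (amplitude 0.49, SE 0.052), and its 24 h component in Grain did not pass (0.16, adjusted p = 0.052). ANKRD22 and JMJD1C overlap another annotated gene and are uncertain.

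Genes of the circadian clock differed between the media in level, and for many the difference depended on the time point (8 of 12 core genes and 8 of 13 outputs and modifiers). BMAL1, the activator at the core of the clock, was higher in Grain by 0.99 (SE 0.017, adjusted p = 3.99e-35), at 82.3 ± 5.44 against 41.3 ± 2.02 CPM (n = 18 each). The repressor PER2 was lower (-0.82, SE 0.075), the nuclear receptor gene NR1D1, which overlaps THRA and is uncertain, was higher by 0.64 (SE 0.087), and the output genes NFIL3 and USP2 were higher by 0.74 (SE 0.015) and 0.79 (SE 0.033). Of the 12 core clock genes tested, 8 were higher in Grain and 4 lower (camera adjusted p = 0.321), and of the 13 outputs and modifiers 7 were higher, 5 lower and BHLHE41 did not pass (0.673). Of the 4 lower core genes, NPAS2 (adjusted p = 0.193) and PER3 (0.176) lost the call without the 6 T12 libraries, and PER3 lost it without any of 9 single libraries, up to 0.0733 without Grain T16 replicate 2.

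A 24 h component was called in 4 of the 12 core genes in Grain, BMAL1 (amplitude 0.09, peak 17.0 h), CLOCK (0.15, 16.3 h), PER3 (0.37, 5.07 h) and NR1D2 (0.20, 3.54 h), and in 2 in Hay, CRY1 (0.21, 3.00 h) and RORA (0.27, 3.15 h). It was called in 6 of the 13 outputs in Grain (among them DBP, HLF, BHLHE40, BHLHE41 and CIART) and in 4 in Hay (HLF, BMAL2, CSNK1D and CSNK1E). Adjusted over the list alone these counts were 4, 2, 7 and 4. PER2 and NR1D1, which oscillate in most tissues, and CRY2 had no called component in either medium (adjusted p = 0.259 or larger), with amplitudes of 0.17 or smaller. With a linear trend added, PER2 (amplitude 0.54, adjusted p = 0.00863), CRY2 (0.19, 0.018) and NPAS2 (0.57, 0.00113) were called in Grain. The test of any difference between time points called more clock genes than the cosine. It added PER2 (0.0304), NPAS2 (0.00189), RORA (0.00447), NFIL3 (1.25e-12), BMAL2 (0.0413) and TIMELESS (0.0218) in Grain. In Hay it added BMAL1 (0.0207), PER1 (0.0321), NR1D2 (0.00555) and BHLHE40 (1.33e-05). With the trend NFIL3 (9.71e-08) and TIMELESS (0.0293) were called in Grain as well, and BHLHE40 in Hay (0.015). The test of the difference was past for CLOCK (adjusted p = 0.0314), PER1 (0.0449), CRY1, NR1D2 (0.0257), BHLHE40 and BHLHE41 (0.0453), and of these CRY1 and BHLHE40 alone kept the call under every alternative tried. That of NR1D2 was lost without Grain T4 replicate 1 (0.0562) or Grain T12 replicate 1, 2 or 3 (0.0655, 0.0679 and 0.0654), and that of CLOCK without Hay T4 replicate 3 (0.0612) or Hay T16 replicate 3 (0.0688). Those of PER1 and BHLHE41 were the least stable, lost without any of 20 and 21 single libraries, up to 0.0948 without Hay T16 replicate 3 and 0.104 without Grain T12 replicate 3. The component of CSNK1D in Hay was lost without Hay T12 replicate 2 (0.051) or Hay T4 replicate 3 (0.053), without the low-count filter (0.0501) and, by more, without the 6 T12 libraries (amplitude 0.04, 0.203). With the replicate number as a block, CLOCK (0.0533), PER1 (0.0655) and BHLHE41 (0.0605) lost the call of a difference. Without the low-count filter NR1D2 (0.0551) and BHLHE41 (0.0784) lost it, and BHLHE41 lost it with DESeq2 size factors too (0.0678). With a linear trend added, PER1 (0.438) and CLOCK (0.0573) lost it and NFIL3 (1.43e-05), NPAS2 (0.00267), BMAL2 (0.00874), BMAL1 (0.0108), CSNK1E (0.0283), DBP (0.0446) and PER3 (0.0483) gained it, so which clock genes differ in their course depends on the model. BHLHE41 lost it without the 6 T12 libraries too (0.228). CRY1 had an amplitude of 0.21 (SE 0.029) in Hay and 0.03 (SE 0.029) in Grain (adjusted p of the difference 0.000963), and BHLHE40 0.37 (SE 0.051) in Grain with a peak at 5.21 h and 0.14 (SE 0.050) in Hay with a fitted peak at 15.0 h (7.31e-05). Both overlap another annotated gene and are uncertain, as do BHLHE41, CIART and CSNK1D.

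**Figure D4:**
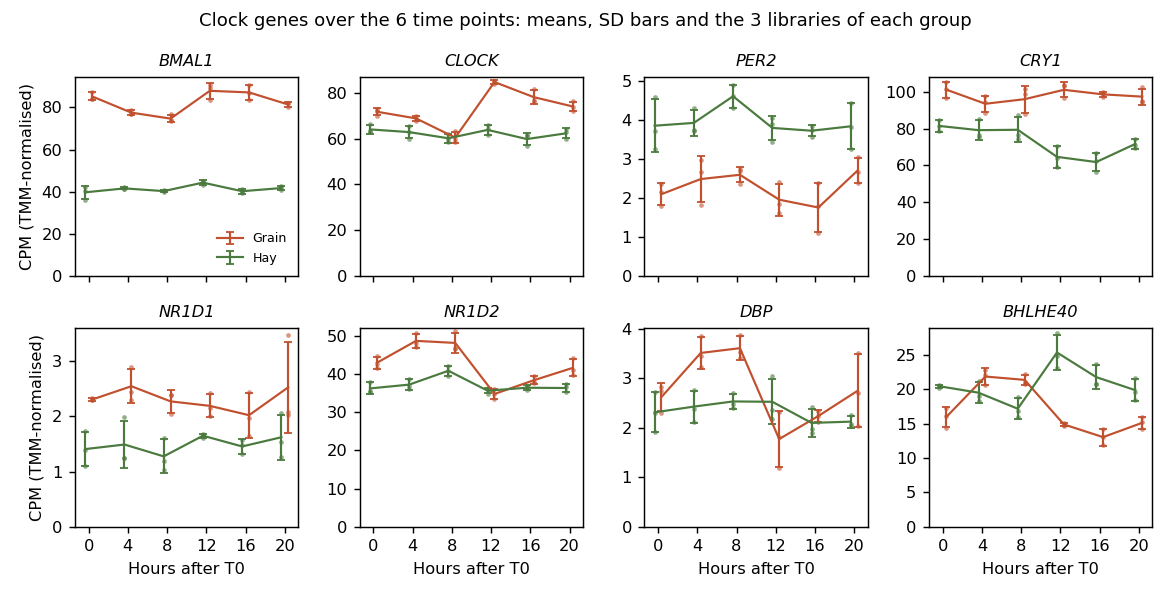
Normalised counts (CPM) of 8 clock genes against hours after T0 in Grain and Hay. Points are the 3 libraries of each group, lines join the group means and bars are SD. BMAL1 lies higher in Grain at each of the 6 time points (82.3 against 41.3 CPM on average), and the largest amplitude of a clock gene in the 24 h fit without a trend was 0.37 on the log2 scale.

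In 26 of 80 list and medium tests the share of genes with a 24 h component differed from other tested genes (Fisher's exact test, two-sided). It was higher in all of these but ribosomal proteins in Grain. Members were not matched to other genes for abundance, which the T8 to T12 change followed (Spearman correlation 0.352 in Grain and 0.326 in Hay). Many lists also rose in that step, 23 of 40 in Grain and 16 in Hay (camera). The part of abundance and of the step in these calls was not tested. In Hay, 50 of 53 ribosomal protein genes were called, against 20.5% of other genes (adjusted p = 4.47e-29), and in Grain 3 of 53, fewer than the 31.9% of other genes (adjusted p = 5.36e-05). The Grain result was lost without Grain T0 replicate 1 (adjusted p = 0.099) or without Grain T20 replicate 3 (0.121). Few cosine calls in Grain do not mean a flat course. From T8 to T12, 41 of 53 ribosomal protein genes rose in Grain (median 0.15) and 53 of 53 in Hay (0.31), and none fell. With an estimated correlation this rise of the list was not called in either medium (camera adjusted p = 0.433 and 0.0536). Cholesterol synthesis had 20 of 23 in Hay (adjusted p = 7.18e-10) and 16 of 23 in Grain (0.002), fibroblast markers 13 of 25 in Hay (0.00256) and 22 of 25 in Grain (2.33e-07), and TGF-beta targets 12 of 19 in each medium (0.000427 in Hay and 0.0202 in Grain). In Hay it was passed too by the proteasome (20 of 31), nuclear oxidative phosphorylation (18 of 27), the TCA cycle (16 of 21), smooth muscle markers (9 of 12), NRF2 targets (15 of 26), immediate early genes (13 of 29) and autophagy (11 of 26). In Grain it was also passed by mitosis (29 of 39), the mitochondrially encoded mRNAs (12 of 13, with 1 of 13 in Hay), short-chain acid oxidation (18 of 25), glucocorticoid targets (13 of 19), desmosomes (13 of 20), heat shock (11 of 16) and histone deacetylase inhibitor targets (10 of 16). In both media it was passed by glycolysis (16 of 20 in Grain, 9 of 20 in Hay) and the unfolded protein response (13 and 11 of 22). Without the 6 T12 libraries, left out after the data were seen, the calls of the proteasome (adjusted p = 0.281) and glycolysis (0.073) in Hay were lost. The mitochondrially encoded mRNAs in Hay then held more called genes than other genes did (5.65e-06), so their contrast between the media rests on T12. Leaving out single libraries ended calls 38 times and gained calls 139 times over all lists. Smooth muscle markers in Grain, not called here, gained a call without Hay T8 replicate 1 (adjusted p = 0.00171), among other libraries. They gained it with DESeq2 size factors too (0.00204). In Grain, desmosomes lost theirs without Grain T0 replicate 1 (adjusted p = 0.0572), heat shock without Grain T4 replicate 2 (0.0623) and the unfolded protein response without Grain T4 replicate 3 (0.0506). Glycolysis in Hay lost it without Grain T0 replicate 1 (0.0684), Grain T0 replicate 3 (0.0651) or Hay T16 replicate 3 (0.0872). TGF-beta targets in Grain lost it without any of 8 libraries, up to 0.0956 without Grain T16 replicate 2, and autophagy in Hay without any of 22, up to 0.231 without Hay T8 replicate 2, and with the replicate number as a block (0.106). Whether a list differs between the media was not tested, and members of a list are not independent of each other. Core clock genes did not stand apart from other genes in either medium (4 of 12 in Grain and 2 of 12 in Hay, adjusted p = 1 in each).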

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

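The tests of the T20 to T0 change, of a common shift and of the order of the time points, both tests of DDIT3 and both tests of the mitochondrial RNAs were chosen only after the result was seen. The test without the most abundant genes and the counts over other splits of the samples were planned before they were run. The step from T8 to T12 that some of them address was itself noticed in the data.

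The difference between the media depended on time for 6 named genes (edgeR adjusted p, 3 libraries per group). SERPINB1 was higher in Grain at T8 (0.50) and lower at T12 (-0.90; adjusted p = 2.48e-22). IL1A (2.67e-21) was lower in Grain by more at T4 (-1.70) than at T12 (-0.38). HSPA1A (3.24e-21), SOX4 (4.57e-21) and SGK1 (4.98e-21) were lower by more at T8 (-1.88, -2.15 and -1.99) than at T12 (-0.32, -1.17 and -0.71). LRRC58 (6.58e-21) was higher by 0.14 at T8 and 2.01 at T12. The 24 h course differed between the media for HNRNPLL (amplitude 0.29 in Grain and 0.19 in Hay, 1.81e-06). It differed for MPV17L (0.12 and 0.24), ANKRD22 (0.31 and 0.27), DGCR8 (0.11 and 0.35), RASL11B (0.16 and 0.38) and SERPINB1 (0.16 and 0.49) at 5.16e-06 each. It differed for SLC66A3 (0.17 and 0.15, 6.82e-06), for THRAP3 (0.07 and 0.16) and JMJD1C (0.14 and 0.23) at 7.59e-06 each, and for RAP1GDS1 (0.13 and 0.15, 1.02e-05). Among clock genes it differed for BHLHE40 (0.37 in Grain and 0.14 in Hay, 7.31e-05), CRY1 (0.03 and 0.21, 0.000963), NR1D2 (0.20 and 0.06, 0.0257), CLOCK (0.15 and 0.02, 0.0314), PER1 (0.11 and 0.11 with peaks at 17.1 and 3.38 h, 0.0449) and BHLHE41 (0.21 and 0.04, 0.0453). Of these, NR1D2 lost the call without Grain T4 replicate 1 (0.0562) and CLOCK without Hay T4 replicate 3 (0.0612), as without a few other single libraries. CLOCK (0.0533) lost it with the replicate number as a block too, as did PER1 (0.0655) and BHLHE41 (0.0605). Without the low-count filter NR1D2 (0.0551) and BHLHE41 (0.0784) lost it. With a linear trend added PER1 (0.438) and CLOCK (0.0573) lost it, and 7 other clock genes gained it. PER1 and BHLHE41 were the least stable, lost without any of 20 and 21 single libraries (up to 0.0948 without Hay T16 replicate 3 and 0.104 without Grain T12 replicate 3).

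Expression changed more between T8 and T12 than between any other neighbouring time points, in 11245 genes in Grain and 8110 in Hay. A 24 h sine alone, or processing in a pair of batches with no other change over time, is argued against by the T20 to T0 change. Its slope on the T8 to T12 change was 0.070 in Grain and -0.182 in Hay, where a full reversal needs about -1. A pair of batches with a further change over time within each can also give a small slope. The slope therefore cannot decide on such batches, which stay open. Leaving out the 20 most abundant genes kept 98.5% of the calls in Grain and 98.6% in Hay, but it decides nothing, because TMM already allows for such genes and the median fold change moved by 0.01 in each medium. Their share of the counts rose from 15.0% to 19.0% in Grain and from 15.1% to 16.7% in Hay, which can shift all other genes by -0.07 and -0.03. Of the calls, 89.4% in Grain and 98.5% in Hay lay beyond such a shift by more than 2 SE. This test decides nothing either, since TMM already allows for such a shift and the calls were picked for lying away from 0. It shows only that most calls were larger than the shift, with a median size of 0.47 in Grain and 0.34 in Hay. A break followed by a gradual return cannot be decided. In the order T12, T16, T20, T0, T4, T8, 5 of 5 changes fell in Hay and 4 of 5 in Grain. In Grain T20 (0.326) and T0 (0.338 ± 0.041, SD, n = 3) lay within the spread. T0 to T8 were harvested before T12, so a return from T20 to T0 was not observed and a 24 h cycle must be assumed. The genes were picked for a T8 to T12 change in the other medium, which favours T12 at the top and T8 at the bottom. Other differences in handling between harvests were not tested, and a time course of the cells themselves stays open beside them.

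DDIT3 differed between the media and varied widely among Hay libraries. Reads passing between DDIT3 and LOC541600 are consistent with that spread: the SD of the summed log2 count within Hay groups was 0.104, against 1.86 for DDIT3 alone. They are argued against as the whole difference between the media, since the sum was still higher in Grain by 3.75 (SE 0.027). A response of the gene to the medium stays open, with the share of reads from each gene unknown.

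The mitochondrially encoded mRNAs were lower in Grain. Scaling is argued against, since the median of the 13 lay at -1.54 relative to the median of all tested genes. The 2 mitochondrial rRNAs did not fall with the mRNAs and were higher in Grain by 0.24 (SE 0.025) and 0.34 (SE 0.021) on average. Whether they follow total mitochondrial RNA is not known. In Hay their share of the counts was 0.380% to 0.392% at T8 and 0.171% to 0.213% at T12, while the mRNAs rose (median 0.40). They therefore do not decide whether there was less of all mitochondrial RNA. At single time points the Grain minus Hay differences of the rRNAs lay between -0.14 (SE 0.061) and 0.73 (SE 0.051), lowest at T8 and highest at T12. The median of the mRNAs stood at -1.96 and -1.29 there. Less of all mitochondrial RNA stays open beside a response to the medium. So does different capture or survival of these mRNAs in library preparation, which was not tested.

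Chance assignment of single libraries can be excluded for the mean comparison, since 1 of 100 splits, the real one, gave 18388 genes and the highest other gave 12759. Whether these libraries are separate cultures is not stated, so this holds for libraries only. For the 24 h component, 1 of 100 splits was as large in Grain (7157 genes, highest other 1633) and in Hay (4647, highest other 916). The same held for the different rhythm (2550, highest other 2). These splits dealt single libraries over the time points and broke up the 3 libraries of a group. Any difference between harvests would exceed them, so they cannot tell a 24 h course from another difference between time points. For the interaction, 2 of 100 splits gave as many as 7322 genes, and the other gave 15132, which points to a structure of the samples, since splits that exchange the media at some time points carry the difference between media into the interaction. With 3 libraries against 3 the splits are too few for a share under 0.05: T0 gave 14127 genes with 1 in the highest other, T4 12987 with 0, T8 12766 with 0. T12 gave 14463 with 1, T16 14108 with 0, T20 13238 with 2, the step from T8 to T12 in Grain 11245 with 2 and in Hay 8110 with 1.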

How the results depend on the processing

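The fits without the 6 T12 libraries and all alternatives of the rhythmic-member lists were chosen only after the result was seen. A minimum fold of 2 lowered the genes that differ from 18388 to 4887 for the mean and to 4440, 3172, 2924, 4674, 4431 and 3411 at T0 to T20. Any difference between time points gave 11579 genes in Grain and 7927 in Hay in place of the 24 h cosine, and a linear trend gave 4343 genes with a different rhythm in place of 2550. For these the cause was not tested. An estimated correlation left 9 lists, for a cause not tested. Fry called 36, as it compares a list with no other gene, and gave the immediate early genes the other direction (adjusted p = 0.0301). Without the low-count filter 44 in place of 26 of the 80 list and medium tests of rhythmic members were past. More genes were then compared while 7108 in place of 7157 were called in Grain, so the share called among other genes was lower there. How far this made the added list calls was not tested. Without T12 the mitochondrially encoded mRNAs in Hay changed direction (Fisher's exact test, adjusted p = 5.65e-06), for a cause not tested.

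The remaining alternatives stayed within 1.5 times of each count, but with the 18 libraries of a medium fitted alone the order of the media turned, 5054 rhythmic genes in Grain and 6233 in Hay. Of the others, DESeq2 gave 18493 genes for the mean, 8070 for the interaction and 3234 for the different rhythm, and DESeq2 size factors 18441 (8163 higher, 10278 lower). Leaving out each library gave 18243 to 18370 genes for the mean, 13360 to 14162 at T0, 12152 to 13044 at T4, 11985 to 12816 at T8, and 13684 to 14509 at T12. It gave 13352 to 14134 at T16, 12411 to 13291 at T20, 6834 to 7413 for the interaction, 6355 to 7681 for the 24 h component in Grain, and 3932 to 4765 in Hay. It gave 2167 to 2855 for the different rhythm, 14 to 16 clock genes, 14 to 15 lists and 25 to 33 of the 80 list and medium tests of rhythmic members.

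Of 331 results of named genes, 300 changed under no alternative, 11 were lost under some and 20 gained. Apart from the clock genes, these genes were picked by size or small p in these data, so their calls were likely to hold. Some alternatives also covered only part of the 331 results. The share that held is therefore no measure of how firm other genes are. The different rhythm of BHLHE41 (adjusted p 0.0557 to 0.104) and PER1 (0.0506 to 0.0948) was lost without any of 21 and 20 single libraries, and the mean difference of PER3 (0.0518 to 0.0733) without any of 9. Larger losses came with a linear trend for PER1 (0.438) and without the T12 libraries for BHLHE41 (0.228), PER3 (0.176) and the mean difference of NPAS2 (0.193). The different rhythm of CLOCK was lost without Hay T4 replicate 3 (0.0612) or Hay T16 replicate 3 (0.0688).

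Replicate numbers did not pair the libraries: 4 of 18 same-numbered pairs correlated over 0.1 (-0.27 to 0.25), and 5 of 18 Grain libraries lay closest to their own number. The replicate block gave 18362 genes for the mean, 7309 for the interaction, 6646 and 4201 for the 24 h component and 2134 for the different rhythm. It ended the different rhythm of CLOCK (0.0533), PER1 (0.0655) and BHLHE41 (0.0605) and the call of rhythmic members of autophagy in Hay (0.106).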

Other observations

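The step between T8 and T12 was noticed in the data, and its genes and lists were chosen only after the result was seen. ACTA2, smooth muscle actin, rose by 2.16 (SE 0.048) in Grain and 2.35 (SE 0.047) in Hay on the log2 scale from T8 to T12, the matrix gene COL6A3 by 1.67 and 1.53, and the actin gene ACTB by 1.54 in each medium (3 libraries per group, edgeR). MMP12, a metalloproteinase, fell (-1.66 and -1.43), as did the secretory granule genes CHGA (-1.51 and -1.40) and SCG2 (-1.34 and -1.20). Of 5714 genes past the threshold in both media, 4780 moved the same way, 2687 up and 2093 down, where independent lists would share 2017. The change also followed abundance (Spearman correlation with the mean log CPM 0.352 in Grain and 0.326 in Hay), which would give shared directions by itself, and its part in them was not tested. The makeup of the RNA moved as well, with long non-coding RNAs at 1.55% to 1.65% of the counts at T8 and 1.07% to 1.09% at T12 in Grain, and 2.25% to 2.29% and 1.55% to 1.65% in Hay. The list changes that follow were not adjusted for either. Of 40 lists 23 rose and none fell past the threshold in Grain (camera), and 16 rose and none fell in Hay. With an estimated correlation 16 rose in Grain and 9 in Hay, and none fell. The groups named here are thus part of a wider rise of the lists. Fibroblast and mesenchymal markers rose together, 23 of 25 in Grain (camera adjusted p = 1.03e-52, and 3.85e-05 with an estimated correlation) and 20 of 25 in Hay (2.19e-47 and 2.67e-05), as did smooth muscle markers, 10 of 12 in Grain (6.17e-19) and 11 of 12 in Hay (3.09e-65). Basal keratinocyte markers rose too, 14 of 16 in Grain (2.97e-23, and 0.000325 with an estimated correlation) and 9 of 16 in Hay (1.3e-10 and 0.0128), so the step was not confined to mesenchymal and muscle markers. Cholesterol synthesis genes rose in 19 of 23 in each medium. The mitochondrially encoded mRNAs rose in 13 of 13 in Grain (median 1.18) and 11 of 13 in Hay (median 0.40), the latter lost at an adjusted p = 0.224 with an estimated correlation.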
